A study of Rattus norvegicus with 18 samples.

How the data were processed

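The samples were 18 Affymetrix rat expression arrays, 9 of proximal and 9 of distal colonic mucosa from the same 9 male Sprague Dawley rats, numbered 1 to 8 and 10 in the labels. Per the labels' protocols, the rats ate a modified AIN-93G diet for 10 days, received azoxymethane at 15 mg per kg under the skin and were killed 6 h later. After the outermost part of each end of the colon was discarded, a length of 4 cm was scraped in each region, and 4.5 µg of RNA was used per array. The series describes 10 rats in 2 allocation groups, but the labels used here do not say which rat belonged to which group or how the groups differed, so no comparison was made between them. Rat 9 was not analysed here. The only comparison the labels allow is that of distal with proximal colon.

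The deposited values are probe set signal intensities on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version and any scaling target are not given in the sources used here. The table holds 31099 probe sets, and columns of no sample numbered 0. Choices of test, filter, gene lists, named genes and alternatives were made before the data were examined, except where stated. That plan took the deposited intensities as already scaled between arrays. They were not, since the trimmed mean (2% at each end) ran from 211.2 to 342.4, a ratio of 1.62. Quantile normalization of the log2 values therefore became the main setting, and the deposited scaling an alternative. Quantile normalization gives all arrays the same distribution and removes any overall shift between the regions.

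From the deposited intensities, log2(value + 16) was computed for the 31042 probe sets that are not controls. The pseudocount of 16 understates the fold of genes with low signal, and every fold given is on this scale. The 30% of probe sets with the lowest mean over all arrays (log2 signal below 5.54) were left out, and 21729 were tested. Gene symbols came from the array annotation supplied with the series, which can be old. Of the probe sets that are not controls, 20826 had 1 symbol, 436 had several and 9780 were unnamed here. A table of rat genes (assembly GRCr8), used for names only, held 20764 of the 20826 and changed 0 symbols. No name was taken from a probe set with several symbols. A gene with several probe sets was represented by the one with the highest mean, which gave 11407 genes, 3200 of them with more than 1 tested probe set. For 33 genes, probe sets passed in both directions.

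Distal minus proximal colon was tested with limma (version 3.58.1, in R 4.3.3), with lmFit and eBayes with an intensity trend, on all 18 arrays without a block, two-sided, and with Benjamini-Hochberg adjustment over the probe sets tested. Every adjusted p of a gene is from this limma fit unless another setting is named. The standard errors are limma's moderated ones. Gene lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry over genes, adjusted over 34 lists of at least 5 measured genes out of 35 lists. A list score is the mean log2 signal of its measured members in an array. An exact permutation of the sign of each rat's difference in the list score (512 sign patterns, two-sided, adjusted over the lists) was added after the data were examined. Scores of 12 lists were correlated between the proximal and distal arrays of the rats with Pearson's r and Spearman's rho, by exact permutation of pairings (two-sided), and again without the 2 rats farthest from the median of the proximal score. Other values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

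The text names the 12 genes with the largest difference in each direction among those past an adjusted p of 0.05, at least 2-fold and with the same direction in all 9 rats. Provisional symbols were passed over. It also names up to 4 members of each list with the largest differences among those that passed, up to 2 members with the highest signal, and a fixed set related to DNA damage, azoxymethane metabolism, proliferation and patterning. In that set, Bax, Adh1 and Hoxd13 had no probe set named for them here. Some genes of that set and 1 of the lists, which stays in the counts of lists, are not reported here, and neither are 5 relations of that list, which stay in the adjustment over 6 relations. Members named without a value in the report, to complete a count of 5 or fewer, were chosen after their values were seen.

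The rat numbers pair the arrays because both arrays of a number came from the same animal, per the labels. As a check, deviations from the region means correlated between the arrays of a rat with r from 0.000945 to 0.569 (median 0.226, above 0.1 in 6 of 9 rats), against a median of -0.03 between different rats, and 4 of 9 proximal arrays matched their own rat's distal array best. No array was a copy of another, since at most 0.00643% of probe sets held identical values in any of 153 pairs of arrays. Control probe sets for RNA integrity gave actin 3'/5' ratios of 1.73 to 3.52. Array medians ran from 66.7 to 115 on the deposited scale. The number of arrays limits the precision.

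The fit was tested on simulated arrays with the same sizes as this comparison and 21729 probe sets. It recovered 32 of 48 genes changed by a log2 value of 0.5, 41 of 48 changed by 1, 42 of 43 changed by 2 and 45 of 45 changed by 3, and called 12 of 21484 unchanged probe sets. Of 34 simulated lists, 1 was called, the one that had been shifted. The simulated values were drawn independently for each probe set, without correlation within lists or pairing by rat. In the real lists the correlation estimated by camera reached 0.697. The simulation therefore cannot show how the list test behaves when the genes of a list are correlated.

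Alternatives were rat as a replicate block, rat as a random block, the deposited scaling, arrays centred on their medians, pseudocounts of 1 and 64, no filter, the lowest 50% left out, eBayes without a trend, array quality weights, the mean of a gene's probe sets, and each rat left out in turn. Alternatives chosen after seeing the data left out the 3 arrays with a high smooth muscle score, left out the proximal arrays of rats 3 and 6, or used the smooth muscle score as a covariate with and without rat as a block.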

Results

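Gene expression was measured in scrapings of the colonic mucosa of 9 male Sprague Dawley rats, each sampled in the proximal and in the distal colon, on 18 Affymetrix rat arrays. All rats had eaten a modified AIN-93G diet for 10 days and were killed 6 h after a subcutaneous injection of azoxymethane at 15 mg per kg body weight. Azoxymethane is a colon carcinogen that alkylates DNA after it is activated in the body. The 9 proximal and 9 distal arrays carry rat numbers in their labels, so every rat contributed 1 array to each region. The number of arrays limits the precision of every value. No untreated rats were among the samples used here, so the values describe the 2 regions after azoxymethane and say nothing about what the injection itself changed. The deposited signals had a trimmed mean of 303.9 ± 31.1 in proximal colon and 284.2 ± 45.6 in distal colon (SD, n = 9 each), and it ran from 211.2 to 342.4 over the arrays.

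The comparison between the regions asks which genes were transcribed differently along the length of the colon at this time. Scgb1a1, which encodes a secretoglobin best known from airway club cells, was 37.0-fold higher in distal colon. Distal colon was also 17.9-fold higher in Fxyd4, a regulator of the sodium-potassium pump, 17.1-fold higher in Hoxb13, the most posterior member of the Hoxb cluster, and 14.3-fold higher in Atp12a, the colonic proton-potassium pump. Low values in the proximal arrays of rats 3 and 6 enlarge these folds. Log2 signals there were 6.01 and 5.33 for Fxyd4, against 7.13 to 10.43 in the other proximal arrays. They were 4.57 and 4.27 for Hoxb13 (6.65 to 9.57 in the others), and 5.05 and 5.29 for Atp12a (7.97 to 9.99 in the others). Proximal colon was 52.1-fold higher in Cyp4f1, a fatty acid hydroxylase, 34.3-fold higher in Saa3, an acute-phase serum amyloid, and 25.5-fold higher in Fabp1, the liver-type fatty acid binding protein. Ghrl, the precursor of the hormone ghrelin, was 20.4-fold higher in proximal colon, and Reg3g and Reg3b, antibacterial lectins, were 19.1-fold and 15.6-fold higher there.

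Scgb1a1 had a mean log2 signal of 7.28 ± 1.18 in proximal and 12.49 ± 0.64 in distal colon (SD, n = 9 each; limma adjusted p = 1.13e-08). For Hoxb13 the means were 7.77 ± 2.08 and 11.87 ± 0.16 (adjusted p = 5.99e-05), with a spread in proximal colon that was far wider than in distal colon. Cyp4f1 went from 11.44 ± 0.45 in proximal to 5.74 ± 0.23 in distal colon (adjusted p = 9.71e-16), and Saa3 from 12.53 ± 0.30 to 7.43 ± 0.24 (adjusted p = 6.96e-17). The other genes among the 12 largest differences toward distal colon were Slc46a1, the intestinal folate transporter (16.6-fold), Eno3 (13.3-fold), Hoxd10 (11.3-fold), Sftpd (10.9-fold), Thbs4 (10.1-fold), Fmo2 (7.98-fold), B3gnt7 (7.79-fold) and Chst5 (7.63-fold). Toward proximal colon they were Dpep1, a brush border dipeptidase (19.3-fold), Hsd17b6 (19.1-fold), Dmbt1 (14.0-fold), Osr2 (13.4-fold), Sptssb (12.9-fold) and Fabp2, the intestinal fatty acid binding protein (10.4-fold). Sftpd and B3gnt7 also had their lowest proximal signals in the arrays of rats 3 and 6, which enlarges their folds, while Hoxd10 was high in that of rat 3 (9.43). All 24 genes differed in the same direction in 9 of 9 rats.

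**Figure D1:**
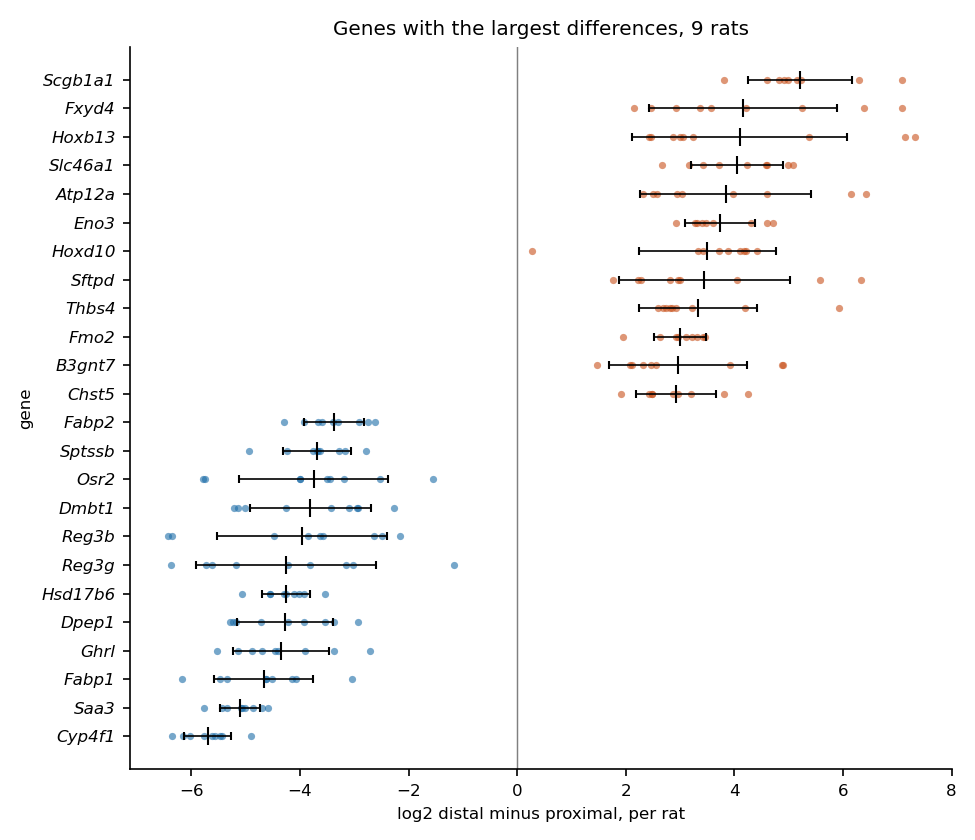
Log2 difference between distal and proximal colon (quantile normalized, pseudocount 16) of the 12 genes with the largest difference in each direction, with 1 point per rat, in orange for genes higher in distal and in blue for genes higher in proximal colon, and a tick and bar for the mean ± SD of 9 rats. All points lie on 1 side of 0 for each gene, with means from -5.70 for Cyp4f1 to 5.21 for Scgb1a1.

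Among 11407 genes tested with limma, 3510 (30.8%) differed between the regions at an adjusted p below 0.05. Of these, 1853 were higher in distal and 1657 in proximal colon. Differences of at least 2-fold were found for 126 genes higher in distal and 227 higher in proximal colon, and 118 and 206 of them had the same direction in 9 of 9 rats. With the deposited scaling kept, 2003 genes passed, of which 451 (22.5%) were higher in distal colon, against 52.8% after quantile normalization. The deposited scaling placed the median of all genes at a log2 difference of -0.10, against 0.01 after quantile normalization, and 31 of the 80 named genes that passed as higher in distal colon did not pass there. When a gene was represented by the mean of its probe sets, Mdm2, Fas, Hnf4a, Nr5a2, Acot2, Stard4, Ccl22 and Clock did not pass and Ctnnb1 did.

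Genes that pattern the body axis differed in both directions. Of 5 measured posterior Hox genes, Hoxb13 and Hoxd10 were higher in distal colon, while Hoxa11 (1.74-fold) and Hoxa10 (1.45-fold) were higher in proximal colon (3 and 2 adjusted over the list alone). The list mean was 1.30 (median 0.26) higher in distal colon on the log2 scale, in 9 of 9 rats (exact within-rat permutation, adjusted p = 0.0133; camera adjusted p = 0.649). Among 11 anterior and central Hox genes, Hoxd9 was 3.40-fold higher in distal colon, and 5 were higher in proximal colon (1 and 7 adjusted over the list alone). These 5 included Hoxd4 (2.62-fold), Hoxa9 (2.34-fold) and Hoxd8 (2.17-fold), besides Hoxa7 and Hoxb3. The list passed camera (adjusted p = 0.0171, and adjusted p = 0.704 with an estimated correlation) and the permutation (8 of 9 rats, exact adjusted p = 0.0266). Without the proximal arrays of rats 3 and 6 its camera adjusted p was 0.0723. Of 20 intestinal transcription factors, 3 were higher in distal and 5 in proximal colon (3 and 5 adjusted over the list alone). Foxa2 was 2.65-fold higher in distal colon, where Elf3 and Hnf4a also passed. Both were lost with the deposited scaling (adjusted p = 0.507 and 0.258) and with arrays centred on their medians, Elf3 also without the 3 arrays of high smooth muscle score (0.0539) and Hnf4a with the mean of its probe sets (0.0634). Proximal colon had more Osr2, more Nr1h4, the bile acid receptor (1.95-fold), more Cdx2 (1.55-fold) and Cdx1 (1.43-fold), the intestinal homeobox factors, and more Nr5a2. The mean of this list was -0.18 (9 of 9 rats, exact adjusted p = 0.0133; camera adjusted p = 0.701), but its median was -0.03, since Osr2 differed far more than the other members, and the mean was 0.03 over the members left when the lowest 50% of probe sets were left out.

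Azoxymethane damages DNA, so single genes related to DNA damage and stress were examined next. Gdf15, a secreted stress factor, was 1.79-fold higher in distal colon, Aen, a nuclease of the apoptotic response, 1.60-fold, and Mdm2, a ubiquitin ligase, 1.32-fold, and Ccng1 passed as well. These 4 did not pass with the deposited scaling (adjusted p = 0.0516, 0.0556, 0.258 and 0.119). Gdf15 had log2 signals of 6.06 and 6.00 in the proximal arrays of rats 3 and 6, against 7.40 to 8.12 in the other proximal arrays. Aen had 8.37 and 8.09, against 9.07 to 9.62. These low values enlarge both differences. Ephx1, an epoxide hydrolase that also serves detoxification, was 2.39-fold higher in proximal colon, where Fas, a death receptor, was also higher. Cdkn1a, an inhibitor of the cell cycle, differed by a log2 value of 0.55 ± 0.20 (SE, n = 9 each, higher in distal colon in 8 of 9 rats). Cdkn1a did not pass (adjusted p = 0.0539), nor with the deposited scaling (adjusted p = 0.233, log2 difference 0.40). With rat as a block its adjusted p was 0.0382 and without rat 10 it was 0.0384. Its proximal signals were 10.09 and 10.05 in rats 3 and 6 and 11.02 to 11.75 in the other rats. The difference thus rests largely on the proximal arrays of rats 3 and 6. Bbc3, a promoter of apoptosis, had a difference of 0.35 (8 of 9 rats, adjusted p = 0.0579), and an adjusted p of 0.0196 with rat as a block, 0.0482 without rat 3 and 0.0418 without rat 7. With the deposited scaling its difference was 0.26 (adjusted p = 0.342).

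Single genes of the DNA repair list differed in both directions. Of 36 genes, 6 were higher in distal colon, among them Mgmt, which removes alkyl groups from guanine (1.34-fold, 7 of 9 rats), Tdg (1.32-fold) and Neil1 (1.24-fold), and 4 were higher in proximal colon, namely Prkdc (1.30-fold), Msh6, Ogg1 and Parp2 (6 and 4 adjusted over the list alone). Leaving out 1 rat took Ogg1 to an adjusted p of 0.0549 to 0.122 for rats 1, 5, 6, 7, 8 and 10, and Parp2 to 0.0508 to 0.0745 for rats 1, 2, 5, 7 and 8. With the deposited scaling Mgmt (adjusted p = 0.208), Tdg (0.135), Neil1 (0.295), Msh6 (0.0708) and Parp2 (0.101) did not pass. Prkdc did not pass without the proximal arrays of rats 3 and 6 or without the 3 arrays of high smooth muscle score. The list did not pass (mean 0.01, exact adjusted p = 0.694, camera adjusted p = 0.864), and with the deposited scaling its mean was -0.09 and its counts were 0 and 3. Mpg, the glycosylase that removes alkylated purines, differed by 0.06 (adjusted p = 0.707), with a sign that turned under the deposited scaling (-0.04). Of 31 apoptosis genes, Casp1, which processes interleukins (2.80-fold), and Tnfsf10, a death ligand (2.65-fold), were higher in proximal colon. Bid (1.40-fold) and Htra2 (1.21-fold), promoters of mitochondrial cell death, were higher in distal colon, except with the deposited scaling (adjusted p = 0.102 and 0.324). The counts were the same, 2 and 2, when adjusted over the list alone. The apoptosis list had a mean of -0.11 (higher in proximal colon in 8 of 9 rats, exact adjusted p = 0.0204; camera adjusted p = 0.356).

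Cell cycle genes were higher in proximal colon. Of 47 measured, 24 were higher there and 1 in distal colon (31 and 2 adjusted over the list alone). Ccna2, a cyclin of DNA synthesis and mitosis, was 1.88-fold higher in proximal colon, Racgap1 1.87-fold and Ect2 1.76-fold, both of which act in the division of the cell body, and Mki67, a marker of cycling cells, 1.68-fold. Ccnd2, a cyclin of the G1 phase, was 3.64-fold higher in distal colon. Pcna, which clamps the polymerase to DNA, differed by -0.12 (5 of 9 rats, adjusted p = 0.315). The list mean was -0.31 (9 of 9 rats, exact adjusted p = 0.0133). Camera gave an adjusted p of 3.74e-06, and an adjusted p = 0.704 with an estimated correlation.

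The list of xenobiotic metabolism, the handling of foreign compounds, also holds enzymes of lipids. Of its 68 measured genes, 26 were higher in proximal and 9 in distal colon (28 and 10 adjusted over the list alone, and 25 and 2 with the deposited scaling). Besides Cyp4f1, the fatty acid hydroxylase, those higher in proximal colon included Ces2c, a carboxylesterase (5.43-fold), Ugt8, a sphingolipid enzyme (5.24-fold), Cyp4b1 (4.11-fold) and Mgst3 (1.66-fold). Adh1c, an alcohol dehydrogenase, was 1.43-fold higher in distal colon but had an adjusted p of 0.0939 with the deposited scaling. Cyp2e1, which activates azoxymethane in the liver, differed by -0.07 (adjusted p = 0.734) and Aldh2 by 0.01 (adjusted p = 0.973, and a difference of -0.09 with the deposited scaling). Log2 signals of Cyp2e1 were low, at 5.55 to 6.45 over the arrays, near the filter level of 5.54. Its values therefore do not show that the regions were equal. The list mean was -0.40 (9 of 9 rats, exact adjusted p = 0.0133; camera adjusted p = 0.000272, and adjusted p = 0.543 with an estimated correlation).

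Genes of ion and water transport differed in both directions. Of 52 genes, 13 were higher in distal and 18 in proximal colon (15 and 19 adjusted over the list alone), with a mean of -0.04 (exact adjusted p = 0.580; camera adjusted p = 0.148), while fry called the list toward proximal colon (adjusted p = 0.000255). Fxyd4 and Atp12a led toward distal colon, and Slc4a4, a sodium bicarbonate cotransporter (8.54-fold), and Car1, a carbonic anhydrase (5.63-fold), toward proximal colon. Guca2a, a gut peptide that drives chloride secretion, was 1.37-fold higher in proximal colon. Among 52 genes of nutrient, bile acid and short-chain fatty acid handling, 11 were higher in distal and 17 in proximal colon (14 and 21 adjusted over the list alone, and 7 and 17 with the deposited scaling). Slc11a2, the iron transporter (5.01-fold), and Slc15a1, the peptide transporter (4.58-fold), were higher in distal colon, and Mep1a, a brush border protease (1.38-fold), was higher in proximal colon. Distal Slc11a2 was uneven, with log2 signals of 8.96 to 9.80 in rats 1 to 4 and 10.56 to 11.39 in the other rats. Slc15a1 was low in the proximal arrays of rats 3 and 6 (5.11 and 4.77, against 6.83 to 8.12 in the others), which enlarges its fold. This list had a mean of -0.26 (8 of 9 rats, exact adjusted p = 0.0204; camera adjusted p = 0.123).

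Of 45 genes of fatty acid oxidation and ketogenesis, 15 were higher in proximal and 5 in distal colon (19 and 5 adjusted over the list alone). Pparg, a lipid-sensing nuclear receptor (2.47-fold), and Pdk4, which restrains glucose oxidation (2.44-fold), were higher in proximal colon. The 5 higher in distal colon were Acsl5 (1.67-fold), Oxct1, which uses ketone bodies (1.59-fold), Acss2 (1.38-fold), Acot2 and Ucp2. Acot2 had an adjusted p of 0.0670 with the deposited scaling, and Ucp2 did not pass there (0.699), with rat as a block (0.0713), or without rat 1, 3, 4, 5, 6, 7 or 8 (0.0578 to 0.115). The list mean was -0.19 (9 of 9 rats, exact adjusted p = 0.0133; camera adjusted p = 0.00234, and adjusted p = 0.704 with an estimated correlation). Cholesterol synthesis had 8 of 23 genes higher in proximal colon and 2 in distal colon (9 and 2 adjusted over the list alone). Fdft1 (1.74-fold), Msmo1 (1.64-fold), Idi1 (1.62-fold) and Fdps (1.54-fold), enzymes on the way from isoprenoids to sterols, were higher in proximal colon. Tm7sf2 and Stard4 were higher in distal colon, but did not pass with the deposited scaling (adjusted p = 0.115 and 0.224). Stard4 was also lost without rat 1, 2, 3, 6, 7 or 10 (0.0542 to 0.0938), with the mean of its probe sets (0.305), without the proximal arrays of rats 3 and 6 (0.0739) and without the 3 arrays of high smooth muscle score (0.101). The mean of the cholesterol list was -0.21 (9 of 9 rats, exact adjusted p = 0.0133; camera adjusted p = 0.0212, and adjusted p = 0.794 with an estimated correlation).

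Of 20 enteroendocrine genes, 13 were higher in proximal colon and 0 in distal colon (16 and 0 adjusted over the list alone; 13 and 0 with the deposited scaling). Chga and Chgb, proteins of the hormone granules, were 5.12-fold and 4.46-fold higher in proximal colon, and Slc18a1, which loads monoamines into vesicles, 3.72-fold. Their list mean was -1.16 (9 of 9 rats, exact adjusted p = 0.0133; camera adjusted p = 1.44e-08, and adjusted p = 0.0649 with an estimated correlation). Of 36 genes of absorptive colonocytes, 15 were higher in proximal colon, such as Tmigd1 (8.48-fold), Dpep1 and Car1, and Ceacam1, Guca2b and Plac8 were higher in distal colon (15 and 4 adjusted over the list alone), although Plac8 had an adjusted p of 0.993 with the deposited scaling. This list had a mean of -0.56 and a median of -0.13 (9 of 9 rats, exact adjusted p = 0.0133; camera adjusted p = 0.000244, and adjusted p = 0.704 with an estimated correlation).

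Goblet cell genes, of which 31 were measured, included 8 higher in proximal and 2 in distal colon (8 and 2 adjusted over the list alone). Spink4 (7.13-fold), Zg16 (3.65-fold) and Gcnt3 (2.02-fold) were higher in proximal colon, and Muc2, the main mucin of the colon, was 1.15-fold higher there. St6galnac6 and Tff3 were higher in distal colon, Tff3 not with the deposited scaling (adjusted p = 0.119). The goblet list had a mean of -0.24 and a median of -0.05 (8 of 9 rats, exact adjusted p = 0.0266; camera adjusted p = 0.133, and 0.0258 without the proximal arrays of rats 3 and 6, where it was 0.596 with an estimated correlation). Of 20 antimicrobial and regenerating genes, 6 were higher in proximal colon, led by Saa3, Reg3g, Reg3b and Dmbt1, and Wfdc2, Lbp, S100a9 (2.16-fold) and S100a8 (2.06-fold) were higher in distal colon (6 and 7 adjusted over the list alone). Its mean was -0.63 (9 of 9 rats, exact adjusted p = 0.0133) but its median was 0.06, and camera gave an adjusted p of 0.747 toward proximal colon. Of 11 tuft cell genes, Dclk1 (1.68-fold) was higher in proximal colon and none in distal colon, also when adjusted over the list alone (mean -0.23, exact adjusted p = 0.0839; camera adjusted p = 0.179).

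Crypt base and Wnt-responsive genes were split, with 6 of 21 higher in each region (7 in distal and 6 in proximal colon adjusted over the list alone; 3 and 5 with the deposited scaling). Lgr5, a stem cell receptor, was 1.86-fold higher in distal colon, and Cd44 (3.25-fold), Prom1 (1.95-fold) and Znrf3 (1.59-fold) were higher in proximal colon. The list did not pass (mean -0.06, median 0.13, exact adjusted p = 0.543; camera adjusted p = 0.878 toward distal colon). The list of Wnt, Bmp, Hedgehog and Notch signalling also holds Areg, Egf and Tgfa, ligands of the epidermal growth factor receptor. Its values therefore do not describe the named pathways alone. Of its 48 genes, 10 were higher in distal and 5 in proximal colon, also when adjusted over the list alone. Areg, a ligand of the epidermal growth factor receptor (3.56-fold), Bmp2 (2.45-fold) and Sfrp2 (2.28-fold) were higher in distal colon, and the 5 others were Chrd, an inhibitor of Bmp ligands (1.93-fold), Sfrp5, Egf, Jag1 and Tgfa. Apc and Ctnnb1, core genes of the Wnt pathway, differed by -0.10 (adjusted p = 0.236) and -0.07 (adjusted p = 0.230). The mean of this list was 0.09 and its median 0.03 (8 of 9 rats, exact adjusted p = 0.0391; camera adjusted p = 0.747), and with the deposited scaling it was -0.03 with 4 genes higher in distal and 5 in proximal colon.

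Immune signals differed gene by gene. Of 34 cytokine and chemokine genes, 7 were higher in distal colon, such as Cxcl16 (1.87-fold) and Ccl9 (1.79-fold), and 3 in proximal colon, namely Cxcl11 (2.36-fold), Ccl22 and Ccl5 (7 and 3 adjusted over the list alone; 3 and 4 with the deposited scaling). That list had a mean of -0.06 (exact adjusted p = 0.694; camera adjusted p = 0.886). Of 47 interferon-induced genes, 3 were higher in distal and 2 in proximal colon (1 and 1 adjusted over the list alone; 1 and 3 with the deposited scaling). Ifi27 was 2.63-fold higher in distal colon and Cxcl11 higher in proximal colon. Trim25 and Tap1 were higher in distal colon, but did not pass without 1 rat (rats 1, 3, 5, 6 and 8 for Trim25, adjusted p = 0.0554 to 0.0999; rats 2, 3, 5 and 8 for Tap1, 0.0538 to 0.101) or with the deposited scaling (0.224 and 0.235), and Irf1 was 1.34-fold higher in proximal colon except without rat 6 (0.0577). Their mean was 0.06 (exact adjusted p = 0.784; camera adjusted p = 0.886), and -0.05 with the deposited scaling. Of 9 genes of MHC class II presentation, Ctss was 1.11-fold higher in distal colon, and 0 passed when adjusted over the list alone. Ctss did not pass without rat 1, 2, 3, 4, 5, 7 or 10 (adjusted p = 0.0505 to 0.0954) or with the deposited scaling (0.969). The MHC class II list had a mean and a median of -0.02 while camera pointed to distal colon (adjusted p = 0.886; exact adjusted p = 0.945).

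Among 37 immediate early and heat shock genes, 8 were higher in distal and 1 in proximal colon, also when adjusted over the list alone. Nr4a2, a nuclear receptor induced by many stimuli, was 3.32-fold higher in distal colon, and Dusp6, a phosphatase that switches off growth factor signalling, 1.65-fold higher in proximal colon. The list mean was 0.19 (8 of 9 rats, exact adjusted p = 0.0391; camera adjusted p = 0.123), and with the deposited scaling the counts were 1 and 2. Of 17 circadian clock genes, Nfil3 was 1.78-fold higher in proximal colon and Clock 1.18-fold higher in distal colon, also when adjusted over the list alone, Clock not with the deposited scaling (adjusted p = 0.494). The clock list did not pass (mean -0.07, exact adjusted p = 0.202; camera adjusted p = 0.864).

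Markers of cells outside the epithelium mostly did not separate the regions. Of 24 smooth muscle markers, Chrm3 was 1.35-fold higher in proximal colon, and 0 passed when adjusted over the list alone. Chrm3 was lost without rat 3, 4, 5 or 8 (adjusted p = 0.0529 to 0.0660). The muscle list had a mean of -0.23 (exact adjusted p = 0.593; camera adjusted p = 0.672). Of 38 fibroblast and matrix markers, Timp1 and Timp2, inhibitors of matrix proteases (2.01-fold each), were higher in distal colon, and Gpc3 (2.36-fold) and Bgn (2.10-fold) in proximal colon (2 and 1 adjusted over the list alone), Bgn not without rat 1, 5, 6, 8 or 10 (0.0889 to 0.133). The mean was -0.50 (exact adjusted p = 0.272; camera adjusted p = 0.123), and camera passed with rat as a block (adjusted p = 0.0206), without rat 2 (0.0230), without rat 7 (0.00487) and without the 3 arrays of high smooth muscle score (4.07e-05), where 2 markers were higher in distal and 21 in proximal colon. With an estimated correlation the fibroblast list passed in none of these settings (adjusted p = 0.578 to 0.931, and 0.967 with all arrays and no block). Esam (1.93-fold) among 19 endothelial markers and Npy, a neuropeptide (1.81-fold), among 18 markers of enteric neurons and glia were higher in distal colon, also when adjusted over each list alone. The endothelial list had a mean of -0.07 (exact adjusted p = 0.687; camera adjusted p = 0.886) and the neuron and glia list a mean of -0.18 (exact adjusted p = 0.139; camera adjusted p = 0.412).

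Among 20 markers of B and plasma cells, Jchain, the joining chain of secreted antibodies (2.78-fold), and Xbp1 (1.13-fold) were higher in proximal colon, also when adjusted over the list alone, Xbp1 not with the deposited scaling (adjusted p = 0.0562). The list mean lay on the other side, at 0.34 (exact adjusted p = 0.559; camera adjusted p = 0.715). Of 26 T and NK cell markers, Gzma (2.25-fold), Cd7 (1.93-fold) and Gzmb (1.80-fold) were higher in proximal colon, also when adjusted over the list alone, Gzmb not without rat 5, 6 or 7 (0.0519 to 0.0523). Their mean was -0.07 and their median 0.02 (exact adjusted p = 0.849; camera adjusted p = 0.503 toward proximal colon). Of 25 macrophage and dendritic cell markers, Tlr4 (1.87-fold) and Cd14 (1.49-fold), receptors for bacterial endotoxin, were higher in distal colon, except with the deposited scaling (adjusted p = 0.0540 and 0.105), and Clec4a1 (1.44-fold) in proximal colon, also when adjusted over the list alone (mean -0.12, exact adjusted p = 0.580; camera adjusted p = 0.672). Without the 3 arrays of high smooth muscle score, 3 macrophage markers were higher in distal and 6 in proximal colon. Of 15 mast cell and granulocyte markers, S100a9, S100a8 and Prg2 (1.75-fold) were higher in distal colon, and Mcpt10 (1.87-fold), Fcer1a and Kit in proximal colon (3 and 4 adjusted over the list alone). Fcer1a was lost without rat 1, 4, 5, 6, 7 or 8 (0.0677 to 0.105), and Kit with rat as a block (0.0824) or without rat 3, 5, 6, 7, 8 or 10 (0.0502 to 0.128). That list had a mean of -0.03 (exact adjusted p = 0.580; camera adjusted p = 0.771).

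Of 4 red blood cell markers, Hbb (2.80-fold) and Alas2 (1.78-fold) were higher in distal colon, also when adjusted over the list alone (list mean 0.61, too few genes for a list test). Pkp1 (3.40-fold) and Krt7 (1.75-fold), of 8 squamous epithelium markers, were higher in distal colon, also when adjusted over the list alone (mean 0.31, median 0.07, 8 of 9 rats, exact adjusted p = 0.0204; camera adjusted p = 0.267). Of 14 pancreas and adipose markers, Cidec (2.11-fold), Pck1 (1.39-fold) and Cidea (1.38-fold) were higher in proximal colon, also when adjusted over the list alone, Cidea not without rat 6 (adjusted p = 0.0746). Pck1, an enzyme of glucose synthesis, is made by cells of the gut as well as of fat. The mean of this list was -0.65 (exact adjusted p = 0.0812; camera adjusted p = 0.0543), and camera passed with rat as a block (adjusted p = 0.0219), without rat 2 (0.0181), without rat 3 (0.0189) and without the 3 arrays of high smooth muscle score (0.0311). With an estimated correlation it passed in none of these settings (adjusted p = 0.502 to 0.809, and 0.734 with all arrays and no block).

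**Figure D2:**
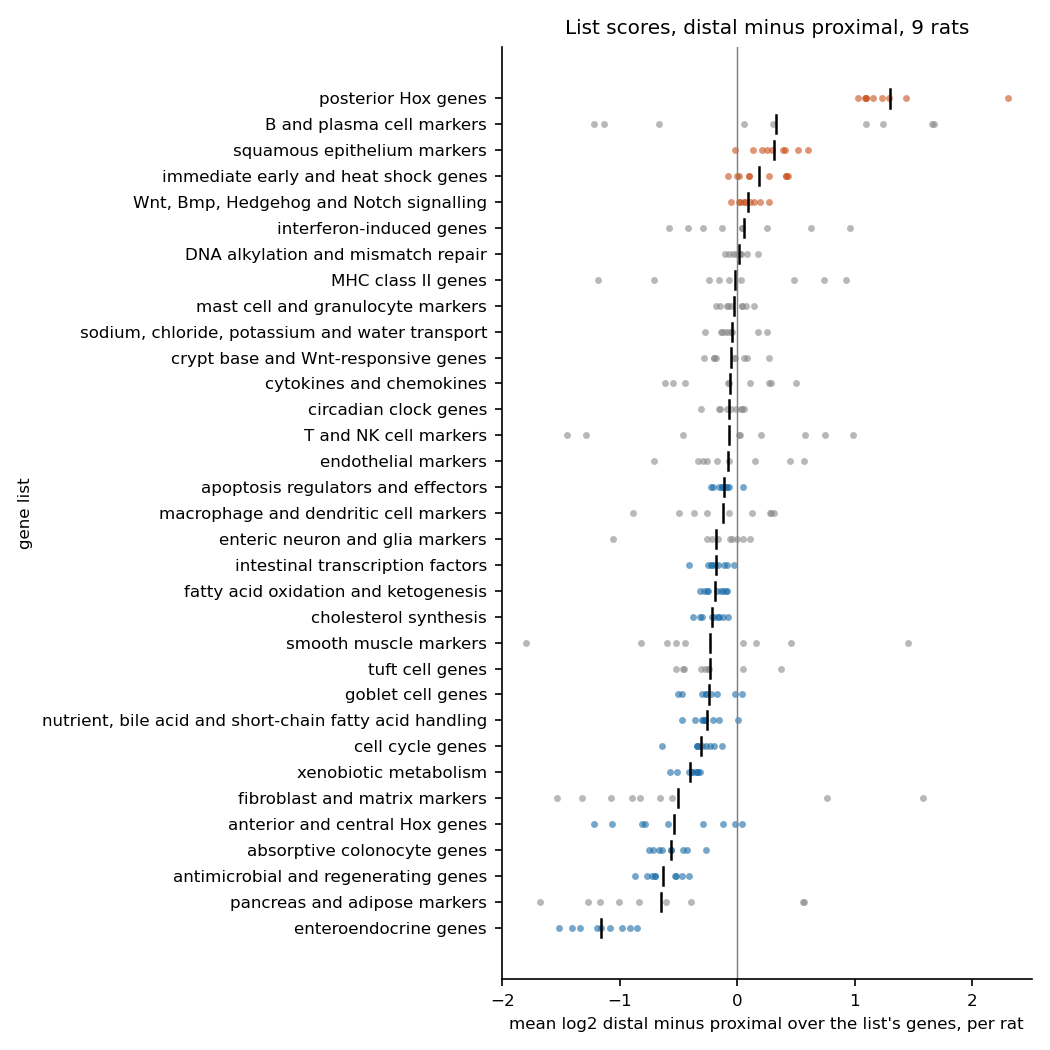
Log2 difference of the list mean between distal and proximal colon, with 1 point per rat and a black bar for the mean of 9 rats. Lists in orange (higher in distal colon) and blue (higher in proximal colon) passed the exact within-rat permutation at an adjusted p below 0.05, and lists in grey did not. Enteroendocrine genes lie at -1.16 on average and posterior Hox genes at 1.30. With the deposited scaling, the means of DNA repair (-0.09), Wnt and Bmp signalling (-0.03) and interferon-induced genes (-0.05) lie below 0.

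In all, camera called 7 of 34 lists, each of them higher in proximal colon, and 0 with an estimated correlation. The fry test, which asks whether the genes of a list move on balance in 1 direction, called 14 lists, 12 higher in proximal and 2 in distal colon, and its mixed test, which takes changes in either direction, called 28. The number of lists camera called was not beyond chance, since 71 of 100 splits of the 18 arrays into 9 and 9, the real one included, called as many. The exact within-rat permutation called 17 lists, 12 higher in proximal and 5 in distal colon. Its smallest possible p was 0.00391, which became an adjusted p of 0.0133. It asks whether a list mean differs between the regions, not whether the list differs more than other genes. Of all genes 30.8% passed limma, and lists drawn at random were not put through this permutation. How many of them it would call is therefore not known. With rat as a block, some counts of members moved by more than 1.5 times. The counts higher in distal and in proximal colon were then 13 and 2 for immediate early and heat shock genes, 6 and 5 for interferon-induced genes, 7 and 6 for antimicrobial genes, 5 and 16 for absorptive colonocytes, 2 and 26 for the cell cycle, 2 and 4 for apoptosis, 3 and 4 for the clock, 2 and 6 for fibroblasts, 3 and 3 for macrophages, 3 and 5 for mast cells and granulocytes, 0 and 2 for tuft cells and for smooth muscle, 1 and 2 for neurons and glia and 1 and 2 for B and plasma cells. With the deposited scaling, list means relative to the median of all genes kept their sign in all 35 lists.

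Some arrays stood apart within their region. The smooth muscle score was 11.07 in the proximal array of rat 3, against a median of 7.59 in the other proximal arrays, and 9.27 and 9.14 in the distal arrays of rats 3 and 7. Fibroblast markers followed (10.05, 9.15 and 9.38 in these arrays). The proximal array of rat 3 also correlated least with its own region (mean r = 0.911, against 0.945 to 0.967 in all other arrays). Hoxb13 had log2 signals of 4.57 and 4.27 in the proximal arrays of rats 3 and 6 and 6.65 to 9.57 in the other proximal arrays. Without these 2 arrays 3364 genes passed. Without the 3 arrays of high smooth muscle score 3487 genes passed, 3039 of them shared with the 3510.

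**Figure D3:**
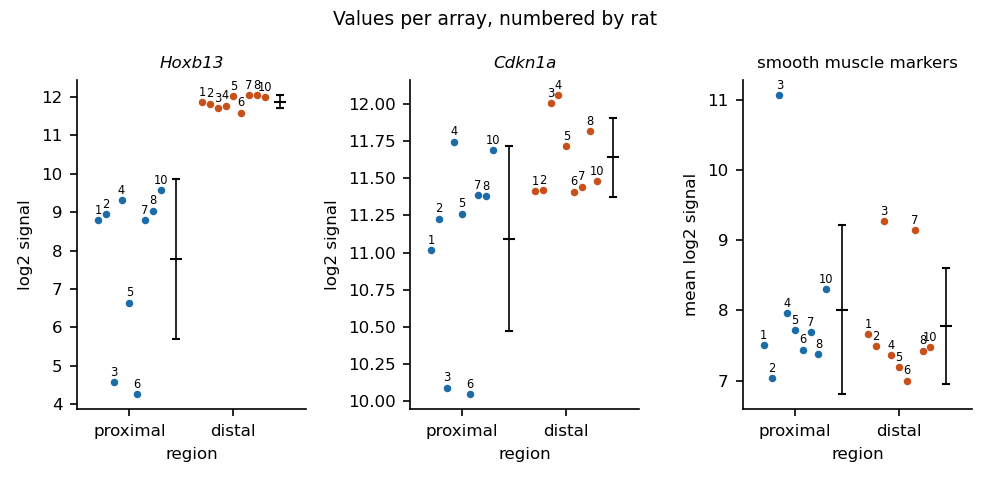
Log2 signal of Hoxb13 and Cdkn1a, and mean log2 signal of smooth muscle markers, in each proximal (blue) and distal (orange) array, with points numbered by rat and a bar for the mean ± SD of 9 arrays. The proximal array of rat 3 has the highest smooth muscle score (11.07), and the proximal arrays of rats 3 and 6 have the lowest Hoxb13 signals (4.57 and 4.27 on the log2 scale).

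Because both regions came from the same rats, list scores could be compared between a rat's proximal and distal array. Over 9 rats and 12 lists, 0 passed after adjustment by the exact permutation of pairings, for r or for rho, and 1 list by r and 3 by rho lay below an unadjusted p of 0.05. Cholesterol synthesis had r = 0.79 (exact p = 0.0132, adjusted p = 0.158) and rho = 0.73 (exact p = 0.0311, adjusted p = 0.147), with r = 0.60 without rat 4, 0.76 without rat 3 and 0.50 without both, and 0.38 with the deposited scaling (adjusted p = 0.554). For cell cycle genes r was 0.63 (exact p = 0.0717, adjusted p = 0.287) and rho 0.80 (exact p = 0.0138, adjusted p = 0.147), with r = 0.56 without rats 10 and 8 and 0.24 with the deposited scaling (adjusted p = 0.644). Smooth muscle markers had r = 0.65 (exact p = 0.0678, adjusted p = 0.287), but r = 0.07 without rat 3 and 0.03 without rats 3 and 2. The other lists reported here had r = 0.56 for circadian clock genes, 0.47 for xenobiotic metabolism, 0.34 for apoptosis, 0.31 for immediate early and heat shock genes, 0.22 for goblet cells, 0.09 for interferon-induced genes, 0.01 for MHC class II genes and -0.26 for B and plasma cells (exact adjusted p = 0.329 to 0.970). Some of these fell or turned without the 2 rats farthest from the median proximal score, to r = -0.56 for xenobiotic metabolism (rats 3 and 10; 0.23 without rat 3 and 0.24 without rat 10), 0.01 for clock genes (rats 10 and 5; 0.24 without rat 10), 0.08 for immediate early and heat shock genes (rats 6 and 10; 0.02 without rat 6), -0.03 for goblet cells (rats 3 and 1) and -0.44 for interferon-induced genes (rats 4 and 5). For B and plasma cells r was -0.70 without rat 10 and -0.11 to -0.15 without rat 5, 6 or 7, and for apoptosis 0.54 without rat 3. Under the deposited scaling r was -0.51 for clock genes, 0.19 for xenobiotic metabolism, -0.04 for apoptosis, 0.25 for immediate early and heat shock genes, 0.53 for smooth muscle, 0.41 for goblet cells, 0.41 for interferon-induced genes, -0.24 for MHC class II genes and -0.51 for B and plasma cells (exact adjusted p = 0.545 to 0.912).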

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

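The tests of RNA quality, of muscle wall in single scrapings, of the site of the scraping and of mixing against each gene's lowest distal array were chosen only after the results they examine were seen. An array was picked out where its gap to the nearest array of its region was large against the region's range, which chance gives in about 1 in 20 groups; 38 of 444 groups were picked out, 20 of them by the proximal array of rat 3 and 5 by that of rat 6.

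In the proximal array of rat 3 the smooth muscle score was 11.07, the fibroblast score 10.05 and the neuron and glia score 7.39, all above the other proximal arrays, while the absorptive colonocyte score was 11.40 and the apoptosis score 8.54, both below them. That array also had the lowest mean correlation with its region (0.911). The distal array of rat 3 had the highest actin 3'/5' ratio (3.52) and the highest Gapdh 3'/5' ratio (1.67). In the proximal array of rat 6 the posterior Hox score was 6.33, below the other proximal arrays.

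Single genes that stood apart in the proximal array of rat 3 were, as log2 signals, Mylk (12.92), Tpm1 (13.16), Kcnma1 (10.25), Hoxd10 (9.43), Hoxd9 (7.48), Sfrp5 (7.08), Sst (8.75), Gcnt3 (10.78) and Aldh2 (11.39) on the high side. On the low side they were Fabp2 (10.78), Mep1a (12.32), Mep1b (10.96), Hnf4a (11.87) and Egr2 (6.92). In the proximal array of rat 6, Ephx1 (10.21), Pparg (10.16) and Mcpt10 (9.16) were high and Hoxa10 (9.18) was low, and in that of rat 2 Slc11a2 (8.17) was high. In the distal array of rat 3, Trim25 (11.77) was high and Fmo2 (7.94), Mgst3 (11.39), Mep1b (11.59) and Tlr4 (9.72) were low. Among the other distal arrays, Bbc3 (9.69, rat 8), Clec4a1 (6.65, rat 7) and Ccl5 (7.42, rat 1) were high, and Clock (9.18, rat 10) and Elf3 (11.33, rat 4) were low.

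Smooth muscle markers were high in the proximal array of rat 3 and the distal arrays of rats 3 and 7. RNA degradation was argued against for 2 of the 3, the proximal array of rat 3 and the distal array of rat 7. Their actin 3'/5' ratios (1.95 and 1.81) lay within the range of the other 15 arrays. It stays open for the distal array of rat 3, whose ratio of 3.52 lay above that range (1.73 to 2.50). Muscle wall in these scrapings remains a candidate explanation, because 9 of 9 fibroblast, endothelial and neuron and glia scores lay above their region's median there. The neuron and glia score barely set the distal arrays apart, at 6.33 (rat 3) and 6.13 (rat 7) against 6.04 to 6.30 in the other distal arrays. Mylk, an abundant muscle gene, was at 12.92, 11.55 and 11.28, against 10.54 to 11.13 and 9.72 to 10.63 in the other proximal and distal arrays. Of the 28 genes of the muscle list, 24 were measured in this mucosa and 0 belong to another list. Muscle wall found no support as the source of the regional differences as a whole, since the smooth muscle score did not separate the regions (mean -0.23, exact adjusted p = 0.593). With that score as a covariate, 99.2% of the 3510 genes stayed called in the same direction. A score that does not follow region could change these calls little, so this share adds little.

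Hoxb13 was low in the proximal arrays of rats 3 and 6 (4.57 and 4.27) and ranged from 6.65 to 9.57 in the other 7. Distal mucosa mixed into all of those 7 was argued against, because in 4 of 7 (rats 1, 4, 8 and 10) at least 10% of the genes that were 4-fold higher in distal colon lay below 50% of the share that Hoxb13 would need, and in 3 of 7 (rats 1, 4 and 10) also against each gene's lowest distal array; Scgb1a1 reached 1.13% to 10.9% of its distal level where Hoxb13 reached 2.25% to 19.8%. Most of these genes did go with mixing, since their median lay at 6.89% to 23.1% of the distal level, at or above that share in 6 of 7, against 4.47% and 4.18% in rats 3 and 6. Mixing therefore stays open for the arrays of rats 2, 5, 7 and 8. Muscle wall in both scrapings was argued against by the smooth muscle score of rat 6, which differed from the median of the proximal arrays by -0.24. The site of the scraping along the proximal colon may differ between rats, since distal-type and proximal-type genes (30 and 40 genes with 4-fold differences) were opposed over the 9 proximal arrays (r = -0.90, exact p = 0.00136, adjusted p = 0.00817 over 6 relations; rho = -0.77, exact p = 0.0214; r = -0.79 without rats 6 and 3). These genes were chosen for their difference between the regions, and other differences between the rats stay open. Distal mucosa mixed into some proximal scrapings would also set the distal-type and proximal-type genes against each other. The sign of this correlation therefore cannot tell site from mixing.

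Of 47 cell cycle genes, 24 were higher in proximal and 1 in distal colon and 22 did not pass, and camera called the list except with an estimated correlation (adjusted p = 0.704). Lymphoid follicles in the proximal scrapings found little support, since the B and plasma cell score was higher in proximal colon in 3 of 9 rats (mean 0.34 toward distal colon, exact adjusted p = 0.559). With this score as a covariate 21 of the 24 called genes remained called, with a list mean of -0.31. That covariate could change little, because the score did not follow region. Scaling of the arrays was argued against by a list mean of -0.32 with arrays centred on their medians. With the deposited scaling the list mean was -0.42, but that scaling shifts the median of all genes by -0.11 in the same direction. Relative to the median of all genes the list was at -0.326 there and at -0.324 after quantile normalization. With the smooth muscle score as a covariate the list mean was -0.31. That score did not separate the regions either (exact adjusted p = 0.593), so muscle wall found no support, but the covariate could change little. A difference in proliferation between the regions may remain as a hypothesis, found and examined on the same data, and a different share of crypt cells in the scrapings was not tested.

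Chance was argued against for the number of genes, although 1 of 100 is the lowest share that these splits can give. Of 100 splits of the 18 arrays, 1, the real one, called as many as 3510, and the highest of the others called 1430. That split and the highest one among splits that part all rats (1764 genes, where again 1 of 100 reached 3510) each had 16 of 18 arrays on their real side. It cannot be excluded for the number of lists called by camera, since 71 of 100 splits called at least 7 lists (highest other 17) and so did 74 of 100 splits that part all rats (highest other 16).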

How the results depend on the processing

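The sign permutation, the smooth muscle covariate and the runs without 2 or 3 arrays were chosen after seeing the data. Of 4397 comparisons of named genes with their value under an alternative, 4184 kept direction and side of the threshold, 179 lost the call, 24 gained it and 10 reversed. For lists these were 796, 1, 25 and 25 of 847, for correlations 168 of 180 kept and 12 reversed, and for counts 177 of 184 stayed within 1.5 times. Where not stated, the cause was not tested.

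With the deposited scaling 2003 genes passed, 451 of them higher in distal colon. This setting shifts the median of all genes by -0.11, and list means turned for DNA repair (-0.0921), Wnt and Bmp signalling (-0.0264) and interferon-induced genes (-0.0462), as did Ctss (-0.0090), Mpg (-0.0370), Aldh2 (-0.0935) and Plac8 (-0.0017). Correlations turned for apoptosis (-0.0419), MHC class II (-0.24) and clock genes (-0.51). Of 174 called named genes, 34 were not called, 31 of which had been higher in distal colon. With arrays centred on medians, and with no filter, camera with an estimated correlation called 1 list. A pseudocount of 64 gave 83 genes at least 2-fold higher in distal colon and 140 genes at least 2-fold higher in proximal colon, since it shrinks folds by construction, and turned the MHC class II correlation (-0.0084).

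With the lowest 50% left out, fewer members were measured and the means of intestinal transcription factors (0.0255), endothelial (0.0829) and T and NK cell markers (0.0089) turned. Array weights turned MHC class II (0.0535), and the mean of probe sets turned Apc (0.0551). Without the proximal arrays of rats 3 and 6, crypt base genes (0.0087), MHC class II (0.0908), smooth muscle (0.127), endothelial (0.128), T and NK cell (0.0134) and macrophage markers (0.0259) and Cyp2e1 (0.0016) turned. The smooth muscle covariate turned MHC class II (0.0140) and endothelial markers (0.0312). The sign permutation called 17 lists. Camera called pancreas and adipose markers with arrays centred on medians (adjusted p = 0.0439), a pseudocount of 1 (0.0421), array weights (0.0347) and the mean of probe sets (0.0274), and goblet cell genes with array weights (0.0488), neither of them with an estimated correlation. Calls lost in several settings were those of Trim25, Ctss, Ucp2, Kit, Fcer1a, Bgn and Mep1b; Chrm3, Cidea, Tap1, Stard4 and Prkdc were lost without the proximal arrays of rats 3 and 6, and Elf3, Hnf4a, Parp2 and Plac8 with arrays centred on medians.

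With 1 rat left out, 3016 to 3666 genes passed. List means ran from -0.14 to 0.13 for MHC class II, -0.0542 to 0.14 for interferon-induced genes, -0.15 to 0.0053 for endothelial markers, -0.19 to 0.11 for T and NK cells, -0.0062 to 0.0288 for DNA repair and -0.13 to 0.0075 for cytokines. Cyp2e1 ran from -0.11 to 0.0082 and Aldh2 from -0.0470 to 0.0939. Correlations ran from -0.0702 to 0.56 for MHC class II, -0.12 to 0.37 for goblet cells and -0.20 to 0.27 for interferon-induced genes. None of these lists, genes or correlations had passed with all rats.

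With rat as a replicate block 4199 genes passed, 3441 of them shared with the 3510, and 4384 as a random block. Among lists the replicate block changed the call of fibroblast (mean -0.50) and of pancreas and adipose markers (mean -0.65) and of no other. Among named genes it gave calls to Cdkn1a, Bbc3 and Mylk and took them from Ucp2 and Kit, and it changed no other call. Genes of low signal have only a bound on their change, because the pseudocount sets their floor.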

Other observations

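The tests in this part were all chosen after the results were seen, and the genes of this paragraph were picked after their values were seen. Transcripts of sodium transport differed in level between the 2 regions. The 3 subunits of the epithelial sodium channel were higher in distal colon, Scnn1g by 5.59-fold (5.97 ± 0.47 in proximal and 8.45 ± 1.48 in distal colon, log2 signal, SD, n = 9 each), Scnn1b by 2.21-fold and Scnn1a by 2.01-fold, each in 9 of 9 rats (limma adjusted p = 0.000528, 0.000279 and 0.00581). The distal arrays were uneven in Scnn1g, at 9.76 to 10.20 in rats 5, 7, 8 and 10 and 6.66 to 7.82 in the other 5 rats, so the mean fold rests largely on 4 rats. The same 4 rats had the highest distal signals of Scnn1b and the lowest of Slc9a3. Scnn1a was low in the proximal arrays of rats 3 and 6 (8.39 and 8.72, against 10.14 to 10.79 in the other proximal arrays), which enlarges its fold. Slc9a3, the sodium-proton exchanger of the brush border, was 3.78-fold higher in proximal colon (12.60 ± 0.20 against 10.69 ± 0.92, adjusted p = 3.99e-05), as was Slc4a2, an anion exchanger (2.56-fold, adjusted p = 1.35e-08). Best2 and Ano1, chloride channels, were 2.92-fold and 2.69-fold higher in distal colon (adjusted p = 4.83e-08 and 6.76e-07). All of these passed with the deposited scaling and without any 1 rat.

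Several hormone precursors were higher in proximal colon beside Ghrl. Gcg, the precursor of glucagon-like peptides, was 3.51-fold higher (8.64 ± 0.59 against 6.82 ± 0.58, adjusted p = 2.19e-05), Sst, which encodes somatostatin, 2.77-fold (adjusted p = 6.23e-06) and Pyy, which encodes peptide YY, 2.17-fold (adjusted p = 0.00549). Neurod1, a transcription factor of endocrine cells, was 3.51-fold higher (adjusted p = 4.59e-07). These 4 differed in the same direction in 9 of 9 rats and passed with the deposited scaling and without any 1 rat.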
